A study of Homo sapiens with 6 samples.

How the data were processed

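The series holds 6 poly(A) RNA-seq libraries of the breast cancer line MCF7, 3 from empty-vector control cells (NF1-EV) and 3 from NF1 mutant cells (NF1-45), all after 24 hours of estradiol. RNA was extracted on silica columns and libraries were made with a KAPA mRNA kit, per the labels' protocols. Reads were trimmed with Trim Galore 0.6.0 and aligned with STAR 2.7.8a to GRCh38, per the submitters' processing notes. The tool that counted reads, the annotation release and the strand setting were not given in the sources used here. The authors deposited a table of raw counts per Ensembl gene and a second table of CPM (counts scaled to a library total of 1e6) for the same genes. The deposited CPM equalled each count divided by the sample's total, within rounding.

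Each table had 60721 rows, of which 40593 carried a gene symbol, and all 6 value columns were used. Genes were matched by Ensembl ID to GENCODE release 29 for coordinates, gene type, exonic length and GC content. The match covered 58503 rows, which held 99.97% of the counts. Total counts ran from 50.2 to 88.1 x 1e6 per sample. A gene with 0 counts allows up to 3 counts, and this floor and the 95% intervals on counts cover counting error only.

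Samples were grouped by the genotype in their titles. The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM scaling, filterByExpr with a minimum count of 10, genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Standard errors were the log2 fold change divided by the square root of F. Levels are means ± SD of TMM-normalised CPM over 3 samples. The NF1 level was also compared with an exact two-sided permutation test. The biological coefficient of variation was 13.7%.

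In all, 34 gene lists on metabolism, signalling, cell identity, other cell types and RNA quality were fixed before the data were examined, as were the design, the named-gene rule and the first set of alternatives. Lists with at least 5 tested genes were compared with all other genes by camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over 33 lists. Camera with an estimated correlation, camera on ranks and fry were run beside it. List medians were placed among 10000 random lists matched on expression. The named genes were NF1; the 10 largest rises and 10 largest falls with a symbol, an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between groups; the 5 smallest p-values in each direction under the same conditions; up to 4 members of each list with the smallest p among those past the threshold, or the 1 with the smallest p; and 10 receptor and RAS pathway genes chosen in advance. Names of genes in the text outside that rule were chosen after their values were seen.

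Alternatives were median-ratio, upper-quartile and library-size scaling, other low-count filters, DESeq2 1.42.0, limma-voom, limma-trend on the log2 of the deposited CPM plus 1, a replicate block, each library left out in turn, a threshold of 0.01 and glmTreat against folds of 1.2 and 2. After seeing the data, 4 more were added: removal of the regional median fold change in 10 Mb windows, thinning of counts to the smallest library, removal of the trend on GC content and length, and protein-coding genes only. The script was tested on simulated counts for the 18534 genes of the NF1-45 versus NF1-EV comparison, with 200 genes changed singly and a list of 30 more shifted together by 1.5-fold. It recovered 23.9% of genes changed 1.5-fold, 58.2% of those changed 2-fold and 93.9% of those changed 4-fold, and 8.22% of all its calls, those in the shifted list included, were unchanged genes. Every pair of libraries differed by more than counting noise, with a chi-square of at least 16.3 per degree of freedom, so no library was counted as a duplicate. The script used no reads, so splicing, allele and mutation questions were not analysed here.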

Results

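Poly(A) RNA was sequenced from 6 samples of MCF7, an oestrogen receptor-positive human breast cancer line. The cells fell into 2 genotypes of 3 samples each, an empty-vector control (NF1-EV) and an NF1 mutant (NF1-45). NF1 encodes neurofibromin, a GTPase-activating protein that switches off RAS. Every sample had spent 3 days in hormone-depleted medium with 10% charcoal-stripped serum and then received estradiol for 24 hours, at 10 nM by the treatment protocol. The sample characteristics gave the dose as 10 mM, and the growth protocol described another medium, so the dose and the medium rest on the treatment protocol and the study's design text. Total counts were 66.7, 88.1 and 71.2 x 1e6 in the NF1-EV samples and 54.7, 50.2 and 55.0 x 1e6 in the NF1-45 samples, so the control libraries were 1.41 times deeper on average. At these depths a gene with no count could lie at up to 0.0340 to 0.0598 CPM, a limit that covers counting error only. Mitochondrial genes took 4.63% ± 0.853 of the counts in NF1-EV and 5.79% ± 0.959 in NF1-45 (SD, n = 3 each). The labels do not say whether the 3 samples of a genotype were separate cultures, or whether either genotype was a single clone, so the p-values below measure only the spread between these samples, which may be technical.

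The first question was whether the NF1 transcript itself differed. NF1 (ENSG00000196712, chromosome 17, 31094927 to 31382116, GRCh38) stood at 129 ± 9.60 CPM in NF1-EV and 44.2 ± 3.91 CPM in NF1-45 (SD, n = 3 each). The mutant level was 34.2% of the control level, a log2 fold change of -1.55 (SE 0.0949, edgeR adjusted p = 1.35e-05). The 3 NF1-45 libraries held 40.3, 44.2 and 48.1 CPM and the 3 NF1-EV libraries 133, 137 and 118 CPM, with no overlap. An exact two-sided permutation test of these values gave p = 0.1, the smallest that 3 against 3 samples can give. The transcript level went in the direction of the labels, although a coding mutation need not lower a transcript.

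**Figure D1:**
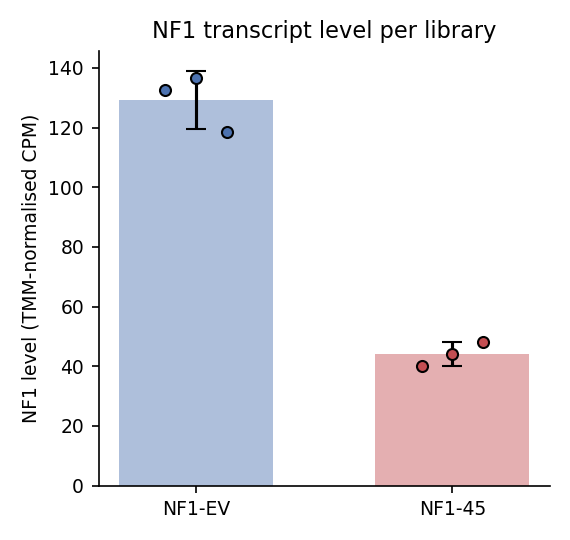
NF1 level in TMM-normalised CPM (y axis, from 0) in each library of both genotypes (x axis); points are single libraries, bars the mean and error bars the SD of 3 libraries. The NF1-45 libraries lie between 40.3 and 48.1 and the NF1-EV libraries between 118 and 137.

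The series title concerns metabolic reprogramming, and the design asked how the transcriptome of NF1-45 cells differed from that of NF1-EV cells under estradiol. Of 18534 genes tested with edgeR, 6758 (36.5%) changed at an adjusted p under 0.05, 3415 higher and 3343 lower in NF1-45. Among them 2469 had changed at least 2-fold, 1579 higher and 890 lower. Protein-coding genes leaned to lower levels, with 2012 higher and 2946 lower of 13625 tested, while the other gene types leaned to higher levels, with 1403 higher and 397 lower of 4909. Scaled on protein-coding genes only, 49.0% of 4780 changed genes were higher, so the lower lean of protein-coding genes depended on the scaling. The even split over all gene types depended on it too: TMM called 50.5% of changed genes higher, library size alone 66.9%, and limma-trend on the deposited CPM 67.7%. Scaling by library size moved the median log2 fold change of all genes up by 0.12. Leaving out single libraries gave between 4521 and 9355 changed genes, the largest number without NF1-EV replicate 3, and the count of higher genes went down to 2189 without NF1-EV replicate 2, 2269 without NF1-45 replicate 2 and 2215 without NF1-45 replicate 3.

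The genes with the largest rises included secreted, signalling and enzyme genes. MUC5AC, a gel-forming mucin (chromosome 11, 1157953 to 1201138), rose from 1.24 ± 1.12 to 28.8 ± 6.77 CPM, a log2 fold change of 4.57 (SE 0.523, edgeR adjusted p = 3.43e-04). That log2 fold change was 5.51 without NF1-EV replicate 1, the control library with the highest MUC5AC level. TNFRSF19, a member of the TNF receptor family, rose from 3.04 ± 0.818 to 35.0 ± 4.15 CPM, and AXIN2, a negative regulator and target of WNT signalling, from 0.583 ± 0.182 to 5.05 ± 0.336 CPM. HPGD, which inactivates prostaglandins, rose with a log2 fold change of 4.02, the complement protease gene C1S with 3.91, CRISP3 with 3.71, the interferon-induced IFIT1 with 3.62 and the ephrin receptor gene EPHA7 with 3.24. MAOB, a monoamine oxidase, rose from 2.97 ± 0.283 to 27.6 ± 1.21 CPM and the carbonic anhydrase gene CA2 from 4.75 ± 0.684 to 41.8 ± 5.76 CPM. The smallest p-values among rises also took in TMPRSS4, a membrane serine protease, and AKR1C2, both with a log2 fold change of 3.07. AKR1C2 and AKR1C1 are near-identical aldo-keto reductases and AKR1C3 a close relative, so the division of reads among them is uncertain.

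Among the falls, NR3C1, which encodes the glucocorticoid receptor (chromosome 5, 143277931 to 143435512), went from 105 ± 17.3 CPM in NF1-EV to 2.38 ± 0.251 CPM in NF1-45, a log2 fold change of -5.46 (SE 0.156, edgeR adjusted p = 8.24e-07). DIO2, which activates thyroid hormone, fell from 16.9 ± 0.534 to 0.500 ± 0.131 CPM, and NT5E, the ecto-nucleotidase CD73, from 37.6 ± 9.01 to 2.64 ± 0.474 CPM. MYPN, a sarcomere protein gene, had 1881 counts over the 3 control libraries and 6 over the 3 mutant libraries, a ratio of 251 (95% counting interval 115 to 685), and its log2 fold change of -7.84 was -8.76 without NF1-45 replicate 1. KLK11, MMP16, PLS3 and CRYBG3 fell with log2 fold changes of -4.60, -4.44, -4.10 and -4.09. The non-coding LINC02732 fell with -4.17 and TENM3-AS1 with -5.15, the latter an antisense gene whose reads cannot be told from those of the opposite strand because the counting strand was not given. The smallest p-values among falls also took in CYP26B1, a retinoic acid hydroxylase (-3.57), the sulphate transporter gene SLC26A2 (-3.18) and the atypical cadherin gene FAT1 (-2.20).

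**Figure D2:**
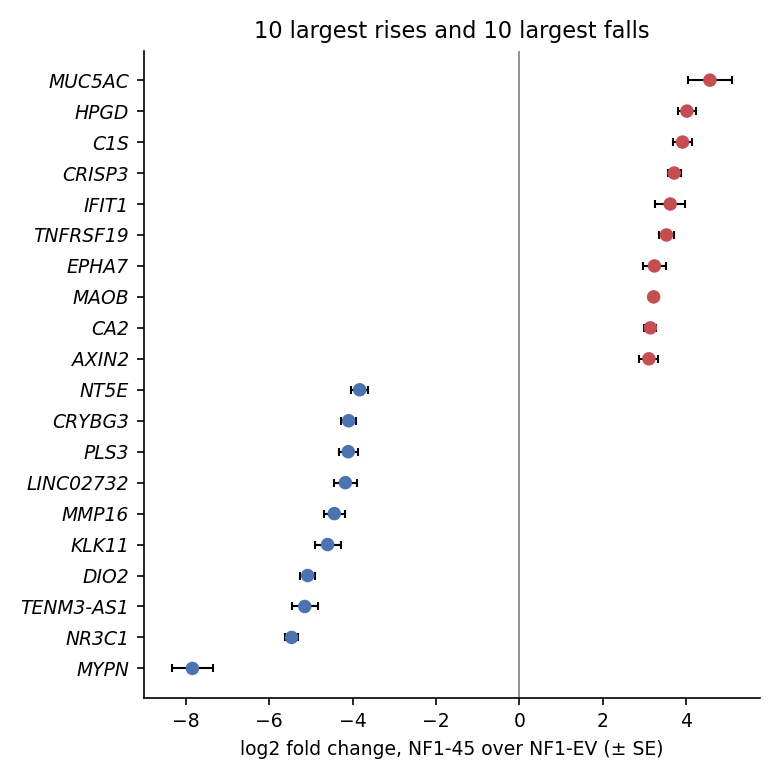
Log2 fold change of NF1-45 over NF1-EV (x axis) for the 10 largest rises and the 10 largest falls chosen by a fixed rule (y axis); points are edgeR estimates and bars ± 1 SE. MUC5AC, at 4.57, and MYPN, at -7.84, are the extremes, and the MYPN value rests on 6 counts in NF1-45.

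RAS pathway output was examined because NF1 restrains RAS. Of 24 tested genes known to rise with RAS and MAPK signalling, 9 rose and 2 fell, the same numbers as adjusted over the list alone, with a median log2 fold change of 0.50. SPRY1, a feedback inhibitor of the pathway, rose from 1.68 ± 0.641 to 5.97 ± 0.406 CPM, and DUSP4, an ERK phosphatase, from 58.8 ± 27.2 to 155 ± 10.9 CPM. TRIB1 rose with a log2 fold change of 0.62, while EPHA4 fell with -0.59. The list lay just past the threshold (camera adjusted p = 0.0466; adjusted p = 0.777 with an estimated correlation), and its adjusted p was 0.0531 without NF1-EV replicate 2, 0.147 without NF1-EV replicate 3, 0.0842 without NF1-45 replicate 3, 0.0909 with library size alone, 0.0664 with upper-quartile factors and 0.0925 with the replicate number as a block. Of the RAS genes, KRAS was lower (-0.73, edgeR adjusted p = 4.35e-04), HRAS was at 0.02 and NRAS at -0.15 (edgeR adjusted p = 0.222; 0.0481 without NF1-EV replicate 1), and SPRED1, which recruits neurofibromin, was at -0.12. SPRED1 was lower past the threshold without NF1-EV replicate 3 (-0.29, adjusted p = 0.0336) and higher with the regional median removed (0.51, adjusted p = 0.0455). KRAS lies on a chromosome whose median was shifted, and its log2 fold change was -0.20 (edgeR adjusted p = 0.122) once the regional median was removed.

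Oestrogen-induced genes were lower on balance. Every sample had received estradiol, so a weaker response to it cannot be told from lower levels without it. Of 30 early oestrogen response genes 16 fell and 4 rose, with a median log2 fold change of -0.44 (camera adjusted p = 0.00402; adjusted p = 0.690 with an estimated correlation). The progesterone receptor gene PGR fell from 219 ± 6.87 to 121 ± 1.13 CPM, GREB1 from 898 ± 110 to 596 ± 11.4 CPM, RET from 294 ± 38.2 to 102 ± 8.35 CPM, and IGF1R from 685 ± 41.2 to 397 ± 17.1 CPM. FKBP4, a steroid receptor chaperone, fell with a log2 fold change of -0.95. FKBP4 and RET lie in shifted regions and were at -0.47 and -1.13 with the regional median removed. TFF1, at -0.52, did not pass (edgeR adjusted p = 0.229), and without NF1-EV replicate 3 it was at -0.86 (adjusted p = 4.06e-04). TFF1 also passed without a low-count filter (edgeR adjusted p = 5.59e-08), a setting that tested 35732 genes, but not by DESeq2 or limma-voom. ESR1, the oestrogen receptor gene, was at 413 ± 38.4 CPM in NF1-EV and 327 ± 24.0 CPM in NF1-45, a log2 fold change of -0.34 (edgeR adjusted p = 0.0218). That call was lost without NF1-EV replicate 2 (0.0672), NF1-45 replicate 2 (0.0652) or NF1-45 replicate 3 (0.103), and for ESR1 also with library size alone (0.112), upper-quartile factors (0.0520), limma-trend (0.119) or the GC and length trend removed (0.0929). Of 19 oestrogen-repressed genes, 4 rose, led by the GABA receptor gene GABBR2 (2.17), and 2 fell, and the list did not pass (camera adjusted p = 0.615). Of 23 luminal identity genes 12 fell and 1 rose, with a median of -0.34 (camera adjusted p = 0.0140; adjusted p = 0.690 with an estimated correlation and 0.0567 with protein-coding genes only). The prolactin receptor gene PRLR fell with -1.73, the androgen receptor gene AR with -1.19, BCL2 with -0.97 and AGR3 with -1.29. ERBB2 and MYC did not differ detectably, at 0.01 and 0.08.

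Genes of central carbon metabolism were lower on balance. Of 23 glycolysis genes 11 fell and 2 rose (14 and 2 adjusted over the list alone), with a median log2 fold change of -0.44 and a camera adjusted p of 0.00325 (adjusted p = 0.777 with an estimated correlation). GAPDH fell from 3167 ± 641 to 1495 ± 147 CPM, the phosphofructokinase gene PFKM from 52.6 ± 7.21 to 20.9 ± 1.14 CPM, PGAM1 with a log2 fold change of -1.19 and ALDOC with -0.94. Of the 11 genes that fell 6 lay in regions with a shifted median, GAPDH, PFKM and PGAM1 among them. With that median removed 8 of the 23 fell and 2 rose, and PGAM1 was at -0.70. Of 73 nuclear genes of oxidative phosphorylation 25 fell and 0 rose at the adjusted threshold (23 and 0 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 6.08e-04; adjusted p = 0.777 with an estimated correlation). The cytochrome oxidase genes COX6A1 and COX7C fell with -0.97 and -0.72 and the ATP synthase gene ATP5F1B with -0.80. Of 27 fatty acid oxidation genes 12 fell and 3 rose, with a median of -0.21 (camera adjusted p = 0.00590; adjusted p = 0.690 with an estimated correlation), among them ETFA (-0.75) and the trifunctional protein gene HADHA (-0.49). Of 25 hypoxia targets, which share glycolytic genes with the first list, 10 fell and 2 rose, with a median of -0.39 (camera adjusted p = 0.00901; adjusted p = 0.690 with an estimated correlation). P4HA1, a collagen prolyl hydroxylase, fell with -1.24 and STC1 with -0.76. The control libraries differed among themselves: the summed CPM of the hypoxia list was 2891, 2506 and 1882 in NF1-EV replicates 1, 2 and 3 and 1948, 1838 and 1931 in NF1-45, and that of glycolysis was 12370, 10864 and 8143 in NF1-EV and 7630, 6957 and 6909 in NF1-45.

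The tricarboxylic acid cycle and fatty acid synthesis lists were weaker. Of 24 tricarboxylic acid cycle genes 9 fell, including IDH2 (-0.78), SUCLG2 (-0.52) and SDHC (-0.44), and IDH3B rose (0.70), with a median of -0.16 and a camera adjusted p of 0.0290 (adjusted p = 0.777 with an estimated correlation). The adjusted p was 0.0794 without NF1-EV replicate 1, 0.0531 without NF1-EV replicate 2, 0.0545 without NF1-45 replicate 3, 0.0651 with library size alone, 0.0721 with a CPM of at least 1 in at least 3 samples and 0.143 with protein-coding genes only. IDH3B lies in a shifted region and was at 0.21 (edgeR adjusted p = 0.0674) with the regional median removed. Of 23 fatty acid synthesis genes 9 fell, including the acyl-CoA synthetase gene ACSL4 (-1.55) and ELOVL5 (-0.45), and 2 rose, with a median of -0.30 and a camera adjusted p of 0.0397 (adjusted p = 0.777 with an estimated correlation). That adjusted p was 0.0892 without NF1-EV replicate 1, 0.0627 without NF1-EV replicate 2, 0.0761 without NF1-45 replicate 3, 0.0882 with the same CPM filter, 0.0509 with the GC and length trend removed and 0.143 with protein-coding genes only.

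Other metabolic lists did not pass the camera threshold, although single members changed. Of 25 glutamine and amino acid genes 9 fell and 3 rose (camera adjusted p = 0.0583). The amino acid transporter gene SLC6A14 fell with a log2 fold change of -2.23 and SLC38A2 with -0.98, while the cystine transporter gene SLC7A11 rose with 1.51. BCAT1, a branched-chain aminotransferase gene, had 170 counts in NF1-EV and 6 in NF1-45, a ratio of 22.7 (95% counting interval 10.2 to 62.7). Of 29 PI3K, mTOR and insulin pathway genes 9 fell and 2 rose (camera adjusted p = 0.0601), with PIK3R1, a regulatory subunit of PI3K, at -0.88 and PIK3R3 at -0.81, both lower by edgeR. Of 24 cholesterol synthesis genes 6 fell and 0 rose at the edgeR threshold (camera adjusted p = 0.281), led by CYP51A1 (-1.11). Of 28 mitochondrial biogenesis and translation genes 6 fell and 0 rose at that threshold (0.308), led by the coactivator gene PPARGC1A, which went from 3.25 ± 1.68 to 0.192 ± 0.0711 CPM. Of 16 serine and one-carbon genes 3 rose and 4 fell (0.745), with PHGDH up by 0.82 and GLDC at -2.20. Of 26 triglyceride genes 3 rose and 3 fell (0.832), with GPAM falling at -0.85. Of 20 nucleotide synthesis genes 2 fell (0.561), including IMPDH2 (-0.32), a call lost without NF1-45 replicate 2 (edgeR adjusted p = 0.0643) or NF1-45 replicate 3 (0.0516), with library size alone (0.0856), by limma-trend (0.0855) or with the regional median removed (0.0694). Of 10 pentose phosphate genes 1, PRPS2, rose (0.745). Of 13 genes encoded by mitochondrial DNA 3 rose and 2 fell (0.661), MT-ND4L falling with -0.52. Leaving out NF1-EV replicate 3 brought the camera adjusted p to 0.0110 for the glutamine and amino acid list, 0.00967 for cholesterol synthesis, 0.0179 for mitochondrial biogenesis and 0.00698 for nucleotide synthesis, and leaving out NF1-45 replicate 1 brought the first of these to 0.0308. The PI3K list reached 0.0309 without NF1-EV replicate 1, 0.00667 with the regional median removed, 6.30e-04 without a low-count filter and 0.0213 by fry. Without that filter the glutamine and amino acid list reached 9.83e-04, cholesterol synthesis 0.0179 and mitochondrial biogenesis 0.0181, and the first of these also reached 0.0474 with library size alone, 0.0494 with upper-quartile factors and 0.0375 by fry.

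Interferon-stimulated genes were the most strongly shifted list. Of 31 tested members 25 rose and 0 fell at the edgeR threshold (26 and 0 adjusted over the list alone), with a median log2 fold change of 1.39 and a camera adjusted p of 1.37e-08 (adjusted p = 0.690 with an estimated correlation). IFIT1 rose from 0.719 ± 0.244 to 8.88 ± 3.79 CPM, IFIT2 with a log2 fold change of 2.31, and the ubiquitin ligase family genes HERC6 and HERC5 with 1.78 and 1.48. Of 13 NF-kB and inflammatory genes 3 fell, among them NFKB1 (-0.42), and the list did not pass (camera adjusted p = 0.340). Of 24 NRF2 antioxidant genes 8 rose, including SLC7A11 and the AKR1C genes, and 2 fell, including the thioredoxin reductase gene TXNRD1 (-0.91), with a median of 0.25 and a camera adjusted p of 0.0273 (adjusted p = 0.777 with an estimated correlation). That adjusted p was 0.0640 without NF1-EV replicate 3, 0.0947 without NF1-45 replicate 1 and 0.0901 with the regional median removed. Of 28 ATF4 stress genes 4 rose, including GDF15 (1.81), and 5 fell, including DDIT4 (-1.58), and the list did not pass (camera adjusted p = 0.688).

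Cell cycle genes were tested as an S phase and a G2/M list. Of 35 S phase genes 6 rose and 0 fell at the edgeR threshold (1 and 0 adjusted over the list alone), with a median log2 fold change of 0.29 (camera adjusted p = 0.0176; adjusted p = 0.851 with an estimated correlation), and PCNA, the sliding clamp of DNA replication, rose from 144 ± 35.7 to 279 ± 18.4 CPM. This list rested on single libraries, with an adjusted p of 0.716 without NF1-EV replicate 3 and 0.0697 without NF1-45 replicate 1, and it had 1 higher gene and an adjusted p of 0.0522 with the regional median removed. PCNA lies in a shifted region, and its log2 fold change of 0.95 was 0.47 (edgeR adjusted p = 0.0573) with the regional median removed. Of 32 G2/M genes 13 fell and 0 rose at the edgeR threshold, with a median of -0.16 (camera adjusted p = 0.00152; adjusted p = 0.777 with an estimated correlation), including KIF23 (-0.79) and CCNB2 (-0.58). Of these 13 genes 9 lay in regions with a shifted median, and with that median removed 7 of the 32 fell and 3 rose. The G2/M median lay at percentile 17.1 of random lists matched on expression, whose own median was -0.10. Of 21 replication-dependent histone genes 8 fell and 0 rose at the edgeR threshold, with a median of -0.58 (camera adjusted p = 0.0140; adjusted p = 0.690 with an estimated correlation), in a family whose near-identical copies share reads. Of 49 ribosomal protein genes, a family with many processed pseudogenes, 12 fell and 2 rose, with a median of -0.13 (camera adjusted p = 7.30e-04, and 0.777 with an estimated correlation). Random lists matched on expression had a median of -0.15, and the ribosomal median lay at their percentile 72.1. By its median this list thus fell no more than equally abundant genes. Of 20 immediate early and heat shock genes 2 rose and 3 fell (camera adjusted p = 0.688).

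**Figure D3:**
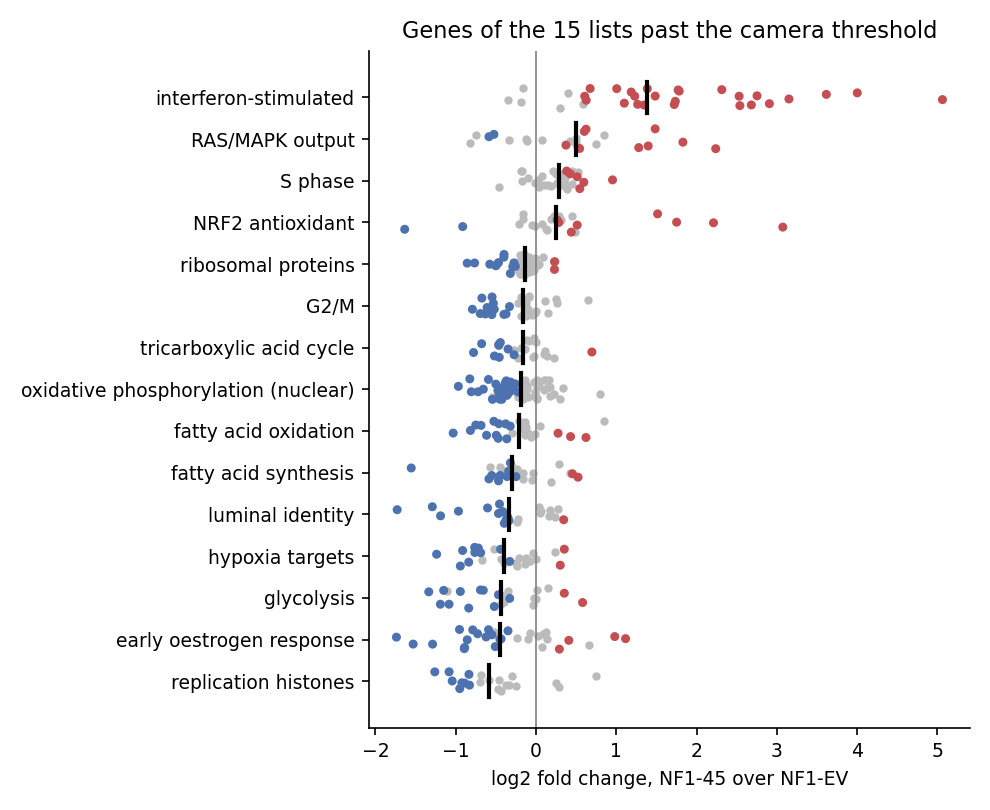
Log2 fold change of NF1-45 over NF1-EV (x axis) for each tested gene of the 15 lists past the camera threshold (y axis); red points rose and blue points fell by edgeR, grey points did not pass, and black bars are list medians. Medians run from 1.39 for interferon-stimulated genes to -0.58 for replication histones.

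Markers of other cell types gave no uniform shift. Of 14 basal and myoepithelial genes 6 fell and 2 rose (camera adjusted p = 0.131), with CAV1 down by -1.19 and the oxytocin receptor gene OXTR up by 2.51. Of 17 mesenchymal genes 3 rose and 3 fell (0.688), with LOXL2 at 1.15 and TGFBI at -1.66. Of 6 tested fibroblast genes 2 rose and 1 fell (0.748), COL3A1 rising with 1.16 and COL5A1 falling with -1.03. Of 5 endothelial genes 1 rose and 2 fell (0.358), with EMCN at 0.87 and ERG at -1.27. Of 8 neural and neuroendocrine genes 1, SYP, rose (0.688). Of the immune genes 3 were tested, too few for the list test, and CSF1R fell, from 68 counts in NF1-EV to 4 in NF1-45, a ratio of 13.6 (95% counting interval 5.08 to 51.4), with a log2 fold change of -3.62 that was -4.92 without NF1-45 replicate 2.

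Of the 33 lists tested, 15 passed with the preset correlation of camera, 4 higher and 11 lower. With a correlation estimated for each list, 0 passed camera and 0 had an unadjusted p under 0.05, the smallest being 0.0615, while fry, which does not compare a list with other genes, called 10, of which 6 were among the 15. Its adjusted p was 0.134 for glycolysis, 0.161 for nuclear oxidative phosphorylation, 0.169 for the tricarboxylic acid cycle, 0.146 for fatty acid synthesis, 0.180 for RAS output, 0.0707 for G2/M, 0.546 for S phase, 0.0608 for histone and 0.0568 for ribosomal protein genes. The other 4 it called were the PI3K, glutamine and amino acid, NF-kB (0.0282) and endothelial (0.0448) lists. The pentose phosphate and neural lists had a median of the opposite sign to their mean and test. Other scalings moved all genes by nearly the same amount, so that 9 lists with medians near 0, none of them past the camera threshold, changed the sign of their median. Some lists past it came near 0 with library size alone. Their medians were then -0.0090 for ribosomal protein, -0.033 for tricarboxylic acid cycle, -0.034 for G2/M and -0.066 for nuclear oxidative phosphorylation genes.

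The fold changes were not spread evenly along the genome. In 10 Mb windows, 9 regions had medians shifted over long stretches (GRCh38 positions, genes above a mean log2 CPM of 1). The median log2 fold change was 0.44 over 112 genes on chromosome 7 from 0 to 30 Mb, 0.46 over 156 genes on chromosome 8 from 0 to 50 Mb and 0.48 over 56 genes on chromosome 20 from 0 to 10 Mb. It was -0.44 over 377 genes on chromosome 10 from 40 to 140 Mb, -0.36 over 655 genes along chromosome 12, -0.39 over 348 genes on chromosome 15 from 30 to 90 Mb, -0.30 over 435 genes on chromosome 14 from 20 to 110 Mb, -0.36 over 97 genes on chromosome 4 from 140 to 190 Mb and -0.25 over 337 genes on chromosome 5 from 90 to 180 Mb. As whole chromosomes, 7, 8, 12, 14 and 15 each had a camera adjusted p of 0.00859 and chromosome 10 of 0.0205 with an estimated correlation, while chromosomes 4 (0.777), 5 (0.197) and 20 (0.122) did not pass. The limits of the 9 regions were set after the values were seen, so a higher share of changed genes inside them was built in. Of the tested genes in these regions 52.5% changed, against 32.3% of genes elsewhere, and 29.8% of all changed genes lay there. Genes elsewhere were not all unshifted: the rest of chromosome 8 had a median of 0.20 over 290 genes. The regions hold NR3C1, MYPN, DIO2, GAPDH, PFKM and KRAS. Of 54 named genes called in these regions, 34 were still called in their direction with the regional median removed, NR3C1 at -5.29, GAPDH at -0.60 and PFKM at -1.07 among them. With the regional median removed 5582 genes changed in all, 59.4% of them higher, and the early oestrogen, glycolysis, nuclear oxidative phosphorylation and interferon lists passed camera as before.

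**Figure D4:**
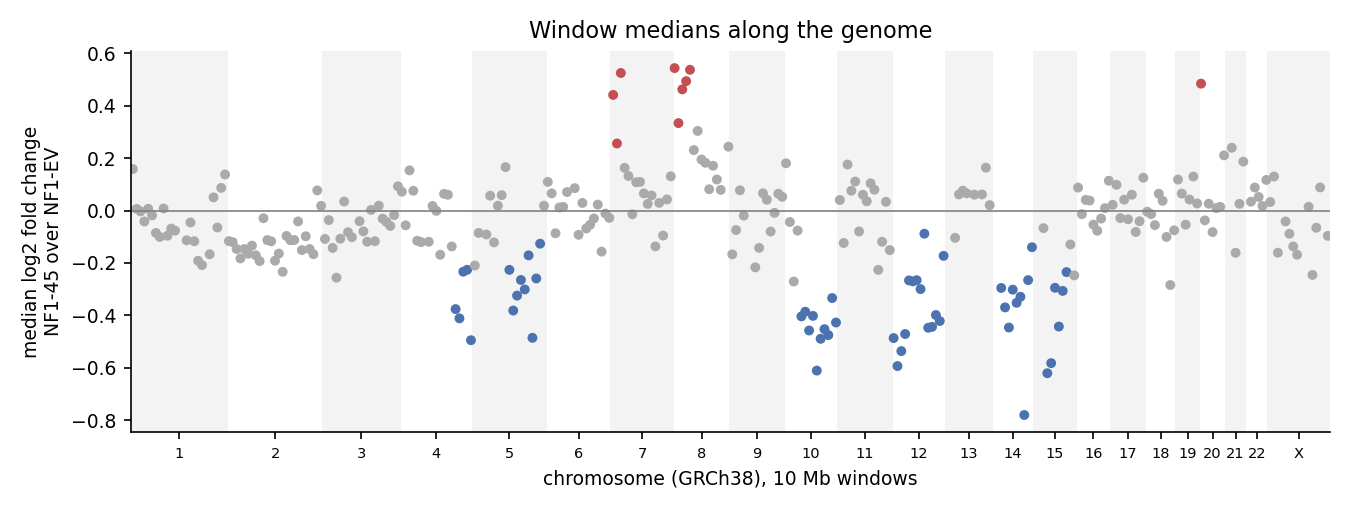
Median log2 fold change of NF1-45 over NF1-EV (y axis) in 10 Mb windows along chromosomes 1 to 22 and X (x axis, GRCh38); each point is a window of at least 10 genes, red and blue points lie in the 9 shifted regions and grey points elsewhere. Regional medians reach 0.48 on chromosome 20 and -0.44 on chromosome 10.

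Non-coding genes were higher on balance. The median log2 fold change was 0.37 over 1132 lincRNA genes, of which 326 rose and 107 fell, 0.93 over 237 sense-intronic genes, of which 120 rose and 2 fell, and -0.05 over 13625 protein-coding genes. By mean expression, the tenth of genes with the lowest levels had a median of 0.46 and the tenth with the highest levels a median of -0.14. The count of genes changed at least 2-fold leaned on such genes, since 1187 genes reached that size among those with a CPM of at least 1 in at least 3 samples.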

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

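NF1 was lower past the threshold under every setting run, with log2 fold changes of -1.62 to -1.49 when single libraries were left out. Among 136 other named genes, 129 kept their direction and 99 also their side of the threshold under all settings. The alternatives chosen after the data were seen were the removal of regional medians or of the GC and length trend, the thinned counts and the protein-coding subset.

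The count of genes changed at least 2-fold moved in several settings: 1187 (714 higher, 473 lower) with a CPM of at least 1 in at least 3 samples, 1237 (687 and 550) with protein-coding genes only, both of which test fewer genes; 670 (414 and 256) by limma-trend on deposited CPM. The glmTreat test counts another quantity, genes shown to exceed a stated fold, and gave 4248 (2003 lower) for a fold of 1.2 and 641 (348 and 293) for a fold of 2. An adjusted p under 0.01 left 3795 changed genes (1795 higher, 2000 lower) and 1031 that were at least 2-fold higher. With each library left out in turn, changed genes numbered 4521 to 9355, higher genes 2189 to 4615, lower genes 2252 to 4740, genes changed at least 2-fold 2013 to 2990 (1192 to 2067 higher, 807 to 970 lower), and gene lists 12 to 16. Camera with an estimated correlation called 0 lists, against 15 with the preset value and 10 by fry, 6 of them among the 15; a correlation estimated from 6 samples is itself imprecise.

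Reversed signs concerned genes near 0, genes in shifted regions and MT-ND3, a called rise (0.45, edgeR adjusted p = 0.0188) on mitochondrial DNA. The MT-ND3 call was lost without NF1-45 replicate 1 (edgeR adjusted p = 0.0551), NF1-45 replicate 2 (0.0836) or NF1-EV replicate 2 (0.0832). With the regional median removed, MRPS16 was at 0.0015, DUT at 0.16, SPRED1 at 0.51, ERBB2 at -0.0337 and HRAS at -0.0212. With the GC and length trend removed, MT-ND3 was at -0.21, ERBB2 at -0.0197, HRAS at -0.11, and the mitochondrially encoded list turned lower (camera adjusted p = 0.0484; over that list's alternatives 0.0484 to 0.932). ERBB2 was at -0.0050 with median-ratio factors, at -0.0050 by DESeq2 and at -0.0478 without a low-count filter, under which HRAS was at -0.0379. SPRED1 was at 0.0109 with library size alone and 0.0225 by limma-trend. With single libraries left out, ERBB2 lay between -0.0840 and 0.0698, HRAS between -0.133 and 0.0889 and MYC between -0.0701 and 0.167. Beyond the regional shift itself, the cause was not tested, for MT-ND3 included.

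The labels do not say whether replicate numbers pair the samples, and the values leave it open. Same-numbered samples had deviation correlations of 0.207, 0.0414 and 0.212. Across genotypes, only NF1-EV replicate 2 correlated better with another number, at 0.136 with NF1-45 replicate 1. With the replicate number as a block 7111 genes changed, 2537 at least 2-fold, 14 lists passed and NF1 was at -1.55; the RAS output list alone changed its call among lists (camera adjusted p = 0.0925) and 0 named genes did. Of the 10 splits of the 6 samples into 3 and 3, which are too few for a share under 0.05, 1 gave as many changed genes as the real 6758, and the highest other split gave 0 by edgeR (1030 at an unadjusted p under 0.05, against 8598); likewise 1 gave as many genes changed at least 2-fold as the real 2469, the highest other giving 0. Every other split put both genotypes in both groups, so a genotype difference raised the spread within them. EdgeR was then bound to call few genes, and these low counts do not measure chance. For lists, 4 splits, the real one included, gave at least the real 15, and the highest other gave 18. The number of lists past camera with the preset correlation thus did not set the genotype split apart from splits that mix the genotypes. Depth limits the genes that can be tested, 17972 after thinning to the smallest library against 18534, and thinning left 6487 changed genes. With 3 samples per group at the real depth the simulation recovered 23.9% of genes changed 1.5-fold. Far fewer genes were changed in the simulation than the 6758 called in the real comparison. Benjamini-Hochberg adjustment sets a stricter cut-off on p when fewer genes change. The simulated share therefore does not give the share recovered in the real comparison, which was not measured.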

Other observations

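Tests on copy number, poly(A) selection, silent-gene density, abundant transcripts, antigen presentation and glucocorticoid targets were chosen after the results they bear on were seen. So were 3 further gene lists, of beta-catenin targets, antigen presentation genes and glucocorticoid receptor targets. Their camera p-values were adjusted over these 3 lists alone, with the preset and with the estimated correlation. Lists fixed beforehand were adjusted over many more, so the adjusted p-values of the 2 families cannot be compared. Whether the beta-catenin list would pass with an estimated correlation in the larger family was not tested. A list of 20 beta-catenin targets, taken after AXIN2 and TNFRSF19 had been seen, had 8 of 15 tested genes higher and 0 lower at the edgeR threshold (camera adjusted p = 1.63e-04; adjusted p = 0.0418 with an estimated correlation), including APCDD1 (2.01), TCF7 (1.03) and LEF1 (0.85). Of 20 tested antigen presentation genes 8 fell, including B2M (-0.88) and PDIA3 (-0.71), both in a chromosome 15 window whose median was -0.58, and 3 rose, including NLRC5 (1.36) and TAP2 (0.66), with a camera adjusted p of 0.0115 (adjusted p = 0.324 with an estimated correlation). Of 19 tested glucocorticoid receptor targets 5 rose, including LCN2 (2.92), PDK4 (1.44) and SGK1 (1.02), and 3 fell, including DUSP1 (-0.56), and the list did not pass (camera adjusted p = 0.865).

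Higher beta-catenin target expression may go with the rise of AXIN2 and TNFRSF19: without those genes the list was still higher, with a camera p of 0.00163 (0.0636 with an estimated correlation) over 13 genes, of which CCND1 also belongs to the RAS output list. Whether the interferon response includes antigen presentation stays open: of its 20 tested genes 8 fell, 9 did not pass and 3 rose, and the list was lower with the regional median removed (camera p = 0.0309, n = 20 genes) but not with an estimated correlation (adjusted p = 0.324). Whether the fall of NR3C1 lowered the 19 glucocorticoid targets cannot be told, since members went both ways (camera adjusted p = 0.865), and the growth protocol named hydrocortisone, a ligand of the receptor, while the medium in the design text was described without it.

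Long chromosome segments were shifted as a block, 3 higher and 6 lower in NF1-45. GC content and transcript length bias argue poorly for this, since 9 of the 9 regions stayed beyond 0.2 in their direction once that trend was removed. A difference in library depth does as poorly, with 9 of 9 beyond 0.2 after thinning. A different number of copies of these segments in the NF1-45 cells stays open: in 9 of 9 regions the expression terciles and all 3 libraries shifted in one direction, but the regions were chosen on these genes and the libraries share their controls, so this outcome was nearly fixed. No DNA data were analysed here, and since either genotype may be a single clone, a difference between clones stays open beside the NF1 mutation.

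Non-coding and low-abundance genes were higher in NF1-45. Thinning left the median of non-coding genes at 0.371 against 0.368 before, which argues against the depth difference. Carry-over of genomic DNA also argues poorly: the summed CPM of 388 olfactory receptor genes was 1.98 times higher, past the ratio of 1.5 set beforehand as a sign of it, but 66.9% of the counts came from 2 genes, 332 genes had no count in any library, and the density of counts over the family was 1.16% of the median excess density of the 1338 higher non-coding genes with a known length. Less complete poly(A) selection stays open, since replication-dependent histone genes, which lack a poly(A) tail, had a median of -0.58, while other classes that mostly lack one were higher, with medians of 1.76 for misc_RNA, 0.88 for snRNA and 0.62 for snoRNA genes. Nuclear RNA content and transcription were not tested and stay open, as does the genotype.

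In NF1-45, 6 metabolic gene lists were lower past the camera threshold, of which 0 held with an estimated correlation (adjusted p = 0.690 to 0.777). Shifted chromosome segments do not account for it alone: with the regional median removed 6 of 6 stayed past the threshold, but the hypoxia median went from -0.39 to -0.23 and that of fatty acid synthesis from -0.30 to -0.18, and the genes that fell went from 25 to 14 for nuclear oxidative phosphorylation and from 12 to 7 for fatty acid oxidation. The falls did not need NF1-EV replicate 3, since 6 of 6 lists stayed past the threshold without it. All 6 medians then went lower, from -0.44 to -0.64 for glycolysis and from -0.21 to -0.25 for fatty acid oxidation. By summed CPM that library was the lowest control in 5 of the 6, so leaving it out could only deepen those falls, and the outcome was nearly fixed. For fatty acid synthesis it stood at 2920, against 3108 to 3539 in NF1-45. Leaving it out cannot tell whether the falls rest on NF1-EV replicates 1 and 2. Without either of these, the tricarboxylic acid cycle and fatty acid synthesis lists did not pass camera, while the other metabolic lists of the 6 did. A general fall of abundant transcripts stays open. Of the 6 medians 5 lay below the 2.5th percentile of matched random lists, with glycolysis at -0.44 against a matched median of -0.09. But the random lists drew each gene separately, while those 5 lists had estimated correlations of 0.0980 to 0.625. That makes the percentiles too extreme, and the 6 lists had been picked as lower in these data. The tricarboxylic acid cycle list lay at percentile 14.3, where such a fall may be enough. With protein-coding genes only, where rescaling moved the log2 fold changes of shared genes up by a median of 0.05, the tricarboxylic acid cycle and fatty acid synthesis lists each had an adjusted p of 0.143, their medians going from -0.16 to -0.10 and from -0.30 to -0.24, and fatty acid synthesis had 0.0509 with the GC and length trend removed; the genotype stays open.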
